A study of Drosophila melanogaster with 6 samples.

How the data were processed

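The deposited count matrices, 1 for each stage, were used as given, and per the file headers and the submitters' processing notes they were made with Cell Ranger 3.1.0 against genome build BDGP6. Each matrix pooled 2 lanes, and the settings used for joining lanes were not given in the sources used here. The matrices held 20038, 28045 and 24044 barcode columns at stages 12, 14 and 16 and 17717 features, of which 17587 were matched by identifier to the annotation used for positions (Ensembl release 115).

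Barcodes carried a suffix of 1 or 2. Those with suffix 1 numbered 10021, 13992 and 12038, and those with suffix 2 numbered 10017, 14053 and 12006. Of the smaller set at each stage, 96.7%, 95.0% and 93.3% were also present with the other suffix. The counts of a pair differed with a dispersion of 0.770, 0.833 and 0.796, where random pairs of barcodes gave 113.96, 729.7 and 819.3, and 46.7%, 43.1% and 41.9% of the entries with 1 UMI under suffix 1 had a UMI under suffix 2. The plan had been to use both suffixes together. After these values were seen each cell was counted once, with suffix 1, and both suffixes together became an alternative.

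Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. This left out 248, 500 and 912 barcodes below the gene minimum and 1853, 3316 and 4837 above the mitochondrial limit. Scrublet called 1, 0 and 2 doublets, so doublet removal cannot be said to have worked in these libraries. The kept cells numbered 8149, 10633 and 7077, with a median of 1433, 879 and 533 genes and a median mitochondrial share of 4.84%, 5.48% and 6.62%.

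The 3 stages were clustered together with scanpy 1.11.5, using 2000 highly variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1.5 with seed 1. Among the classes with at least 3 markers at least 2-fold higher in a cluster than in all other cells, the cluster was given the class with the highest marker score, the mean log2 ratio of its markers. The score had to be at least 1.4, or at least 1 with a marker among the 10 leading genes of the cluster, and no other class could have more markers among those 10. Clusters without such a marker also stayed unnamed where their median depth, as a ratio to the median of the stage, was under 1/3. The marker genes were set before the data were examined and these thresholds afterwards. Of 45 clusters, 31 were named with 16 classes and 14 were left unnamed.

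UMIs were summed over the kept cells of a stage, or of a class with at least 200 cells at both stages compared, and divided by the total to give counts per 1e6 UMIs (CPM). Ratios carry exact conditional binomial intervals, single counts exact Poisson intervals and shares of cells Clopper-Pearson intervals, all at 95%. For a gene without UMIs at the lower stage a floor of 3 counts was used. Gene list medians used members with at least 5 CPM in 1 of the stages and a pseudocount of 0.5 CPM, with 2000 bootstrap draws over members and 10000 random lists matched in 20 expression bins. For a share of 0, the limit given is 3 counts of the cells measured. Shares of cells with a UMI of a gene were measured after thinning each cell to 1000 UMIs without replacement.

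Genes were named by a fixed size rule. In the whole embryo these were the 10 highest and 10 lowest ratios among genes with at least 100 CPM in a stage, without mitochondrial genes and with the same direction under suffix 2. In a class they were the 5 highest and 5 lowest among genes with at least 200 CPM, between the first and last stages with 200 cells. For each list described, up to 4 members with at least 20 CPM and the largest ratios either way were eligible, as was any temporal factor, Hox gene, neurotransmitter identity gene or class marker.

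The steps were tested on simulated data drawn from the stage 12 profile at the depths of stages 12 and 14. The intervals held the true ratio for 95.1% of unchanged genes and 95.5% of 200 changed genes among 7079. These counts were independent Poisson draws, the case the intervals are built for. The test thus checked the calculation and did not cover UMIs that cluster in single cells. A list of 37 genes planted at a log2 ratio of 0.5 gave a median of 0.49, and 1 of 44 other lists lay outside percentiles 2.5 to 97.5. In cells simulated from the cluster profiles of all stages 88.5% of 17405 were given their class again, with 69.7% for epidermis and 60.4% for midgut. These cells were multinomial draws from each cluster and stage, so further variation between cells of a cluster was not covered. After thinning, 96.5% of 200 genes lay within 2 standard errors of the exact share. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, statsmodels 0.14.6 and matplotlib 3.10.9.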

Results

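Whole *Drosophila melanogaster* embryos were dissociated at stage 12 (8 to 9 hours at 25 °C), stage 14 (10 to 11 hours) and stage 16 (15 to 16 hours), and single-cell transcriptomes were measured with droplet 3′ RNA sequencing. The embryos carried a Gal4 driver named for neuroblast 7-1, a neural stem cell of the ventral nerve cord, and a nuclear red fluorescent reporter under Gal4 control. Each stage had 1 count matrix that pooled its 2 lanes, so there were no replicates and no difference between stages was tested. Values are given for each stage with 95% intervals (exact Poisson or exact binomial, Clopper-Pearson) that cover counting error only. Most cell barcodes occurred once with each of 2 suffixes, 9685 at stage 12, 13297 at stage 14 and 11200 at stage 16. For 98.8%, 97.8% and 97.6% of these pairs the totals lay within 10% of each other, and each barcode was therefore counted once, with suffix 1. Whether the pairs were lanes of the same cells that should be joined was not given in the sources used here, and if they were, the UMIs per cell below are lower than the full depth. The comparisons, gene lists and size rules were set before the data were examined, and the use of 1 suffix and the thresholds for naming clusters were set afterwards. After filtering, 8149 cells with a median of 4524 unique molecular identifiers (UMIs) were kept at stage 12, 10633 cells with a median of 1939 at stage 14, and 7077 cells with a median of 1018 at stage 16. The total UMIs of the kept cells were 53418759, 54231590 and 37171049.

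The first comparison asked which cell classes made up the embryo at each stage. Neuroblast-like cells held a smaller share, and neuron-like cells a larger share, at each later stage. Cells in clusters marked by neuroblast genes such as *dpn*, *wor*, *ase* and *mira* were 7.82% (7.24 to 8.42) of kept cells at stage 12, 3.41% (3.08 to 3.78) at stage 14 and 1.91% (1.60 to 2.25) at stage 16. Cells in clusters marked by neuronal genes such as *elav*, *nSyb* and *brp* were 4.69% (4.24 to 5.17), 7.30% (6.81 to 7.81) and 14.3% (13.5 to 15.1). Hemocyte-like cells, the blood cells of the embryo, were 5.37% (4.90 to 5.89), 5.77% (5.33 to 6.23) and 8.69% (8.04 to 9.37). Epidermis-like cells were 1.96%, 9.79% and 19.2%, midgut-like cells 4.92%, 4.77% and 20.2%, somatic muscle-like cells 6.70%, 11.4% and 8.65%, and glia-like cells 1.55%, 2.84% and 2.85%. Mesoderm progenitor-like cells were 5.02%, 1.55% and 1.46%. This class was cluster 1 alone, and its leading genes also included the heart and nephrocyte markers *prc*, *Hand* and *H15*. Its score was 2.57 for mesoderm progenitor and 1.87 for heart and nephrocyte. The class names were rebuilt here from marker genes, and 14 of the 45 clusters, with 48.4% of cells at stage 12, 33.8% at stage 14 and 12.9% at stage 16, stayed unnamed. Unnamed cluster 33, with *mt:ND5* and *mt:CoI* among its leading genes, held 34, 1482 and 17 cells. Its median depth was 0.34 of the median of the stage. Unnamed clusters 34, 7 and 17 held 3, 594 and 2 cells, 773, 309 and 12 cells, and 633, 211 and 7 cells. Unnamed cells count in the total of every share, so clusters 33 and 34 lower the shares at stage 14. Class shares, that of epidermis-like cells included, cover named clusters only. Unnamed cluster 5 held 1172, 162 and 1 cells, with the myoblast fusion genes *sns*, *lmd* and *Vrp1* among its leading genes. The rise of somatic muscle-like cells from 6.70% to 11.4% therefore covers the named clusters only. Unnamed cluster 3, whose nearest class under the naming rule was neuroblast, held 368, 209 and 14 cells. The direction from stage 12 to stage 16 held under every alternative for neuroblast-like, neuron-like and hemocyte-like cells, but its size moved, with log2 share ratios of -2.03 (-2.44 to -1.15 over the alternatives), 1.61 (0.66 to 2.68) and 0.69 (0.39 to 2.06). It turned under at least 1 alternative for epidermis-like, midgut-like, somatic muscle-like and glia-like cells. For example, with each stage clustered on its own the log2 share ratio of epidermis-like cells was -0.46 in place of 3.29, and that of somatic muscle-like cells was -1.47 in place of 0.37.

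**Figure D1:**
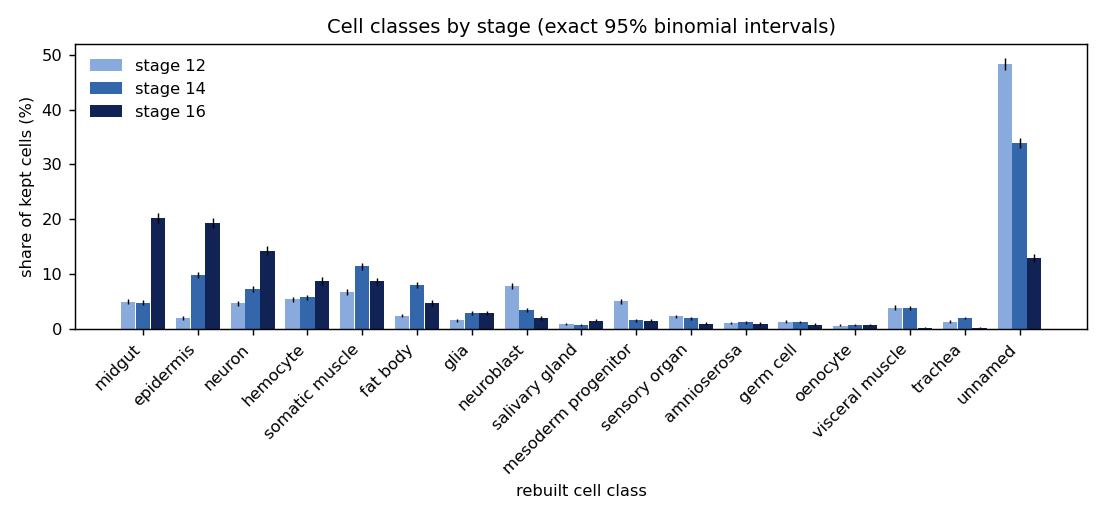
Share of kept cells (%, y axis) in each rebuilt cell class (x axis) at stages 12, 14 and 16; bars are shares and lines are exact 95% binomial intervals. Neuroblast-like cells stood at 7.82%, 3.41% and 1.91%, and neuron-like cells at 4.69%, 7.30% and 14.3%.

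Between stage 12 and stage 14 the whole embryo held more transcripts of cuticle building and of muscle at the later stage, and fewer transcripts of cell division and Notch signalling. All 14 measured Osiris genes, a family of transmembrane protein genes expressed in cuticle-forming epithelia, were at least 2-fold higher at stage 14, with a median log2 ratio of 4.86, or 4.98 relative to the median of all genes, and 3.83 without barcodes over 50000 UMIs. *Osi14* (FBgn0040279, chromosome 3R, 6299128 to 6300738, build BDGP6) stood at 44 and 24047 UMIs, a log2 ratio of 9.07 (8.65 to 9.53), and *Osi20* at 13.6 and 868 counts per 1e6 UMIs (CPM). Of the family, 20 genes lie together on chromosome 3R between 6173549 and 6341424. Of 30 measured cuticle protein genes, 23 were at least 2-fold higher at stage 14 and none was at least 2-fold lower, with a median of 4.05 (4.16 relative), which was 2.95 with cells weighted equally and 6.22 with members of at least 20 CPM. Among them, *Ccp84Ag* had a log2 ratio of 9.79, *Cpr64Ad* 9.69 and *Twdlbeta* 9.20, but 88.8%, 96.6% and 91.0% of their stage 14 UMIs came from 1 cell each. Without barcodes over 50000 UMIs these 3 ratios were 5.53, 4.72 and 3.92. *CG13049* had no UMI at stage 12 and 24440 at stage 14, at least 8025-fold higher, of which 87.8% came from 1 cell. *CG9083* stood at 11 and 16280 UMIs in 1316 cells (log2 ratio 10.51, 9.67 to 11.51). The list of chitin and cuticle assembly genes had a median of 1.42 (15 of 21 at least 2-fold higher), with *dyl*, an apical extracellular matrix gene of the epidermis, at 5.85 and the chitin-binding *Gasp* at 3.08.

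In the same comparison sarcomere genes had a median log2 ratio of 1.37 (1.49 relative), with 13 of 21 at least 2-fold higher and 1 at least 2-fold lower. *Mhc*, the muscle myosin heavy chain, stood at 48.2 CPM at stage 12 and 304 at stage 14, *Prm*, paramyosin, at 4.774 and 44.96, and *up*, a troponin T, at 73.3 and 333. *Act87E*, a muscle actin, was lower at stage 14, at 563 and 143 CPM (log2 ratio -1.97, -2.01 to -1.94). Basement membrane genes had a median of 0.88, with *trol*, perlecan, at 2.13 and the collagen IV genes *vkg* and *Col4a1* at 2.00 and 1.94. Neuronal ion channels had a median of 1.45 (11 of 13 at least 2-fold higher), with the potassium channel gene *SK* at 2.39 and the calcium channel gene *cac* at 2.19, and neurotransmitter receptors a median of 1.65 (8 of 12). Cell cycle genes had a median of -0.84 (-0.72 relative), with 16 of 37 at least 2-fold lower at stage 14 and none higher. *polo*, a mitotic kinase, stood at 46.3 and 15.3 CPM, and *fzy*, an activator of the anaphase-promoting complex, at 40.5 and 13.9. Notch targets and ligands had a median of -1.15 (-1.03 relative), with 11 of 18 at least 2-fold lower, among them *E(spl)mgamma-HLH*, a Notch-induced repressor, at -1.47 and *Brd* at -1.66. *jhamt*, which encodes the enzyme of the last step of juvenile hormone synthesis, stood at 282 and 60.8 CPM (log2 ratio -2.21, -2.27 to -2.16). Other genes with low ratios were *CG13427* (-2.35), *yellow-e3* (-1.57), *Ocho*, a *Bearded* family gene (-1.39), and *Obp99a* (-1.38). Of these, *CG13427*, *yellow-e3* and *Obp99a* were among the leading genes of unnamed cluster 7, with 773 cells at stage 12 and 309 at stage 14. The medians of the cuticle, Osiris, sarcomere, Notch and cell cycle lists lay at percentiles 100, 100, 100, 0 and 0 of 10000 random lists matched on expression, as a description of these libraries. The median of all genes was -0.12 with scaling by total UMIs.

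From stage 14 to stage 16 the embryo's neuronal transcripts and cuticle transcripts were higher, and Notch and segment polarity transcripts were lower. Of 55 measured cuticle protein genes, 46 were at least 2-fold higher at stage 16 and 3 at least 2-fold lower, with a median log2 ratio of 3.28 (3.50 relative). *TwdlB*, a Tweedle cuticle protein gene (FBgn0039436, chromosome 3R, 26622451 to 26623543), stood at 1.55 and 114 CPM (6.21, 5.89 to 6.53), *TwdlM* at 10.6 and 373 and *CG13041* at 4.70 and 369. Of 15 Osiris genes, 14 were at least 2-fold higher, with a median of 2.13. All 9 measured neurotransmitter identity genes were at least 2-fold higher (median 2.10, 2.32 relative), as were 18 of 21 neurotransmitter receptors (2.05) and 15 of 19 neuronal ion channels (1.69). *VGlut*, the vesicular glutamate transporter, stood at 14.0 and 61.4 CPM, *Gad1*, the enzyme that makes GABA, at 5.57 and 27.3, and *DAT*, the dopamine transporter, at 4.19 and 26.7. After thinning to 1000 UMIs, *DAT* was detected at stage 16 in 12.5% of glia-like cells and 2.17% of neuron-like cells, so its rise was not only neuronal. *para*, the voltage-gated sodium channel (FBgn0285944, chromosome X, 16455027 to 16533096), stood at 15.7 and 120 CPM (2.93, 2.82 to 3.04), and *Rdl*, a GABA receptor (FBgn0004244, chromosome 3L, 9145838 to 9182149), at 15.9 and 158. Synaptic vesicle release genes had a median of 0.92 (10 of 23 at least 2-fold higher), with the active zone genes *Rim* at 2.25 and *brp* at 2.07. Neuropeptides and processing genes had a median of 2.40 (14 of 18), which was 0.72 when only members with at least 20 CPM were used.

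Over the same interval 14 of 18 Notch targets and ligands were at least 2-fold lower at stage 16 (median -1.74, -1.52 relative). *Tom*, a *Bearded* family inhibitor of Notch signalling (FBgn0026320, chromosome 3L, 14969344 to 14970306), stood at 415 and 47.7 CPM (-3.12, -3.19 to -3.05). The noncoding *lncRNA:CR43432*, which lies on the same chromosome arm, stood at 426 and 54.4 CPM (-2.97). Segment polarity genes, which pattern each body segment, had a median of -1.12 (6 of 11 at least 2-fold lower), with *gsb* at -1.82, *en* at -1.74 and the Hedgehog receptor *ptc* at -1.46. Cell cycle genes had a median of -0.69 (10 of 35 at least 2-fold lower), with *fzr* at -1.71 and *Cdk1* at -1.21. Basement membrane genes had a median of 0.75, and *Col4a1* stood at 754 and 2873 CPM. The genes with the lowest ratios were *CG13362* (-3.94), *nw* (-3.71), *CG18754* (-3.70), *CG10591* (-3.48), *wbl* (-3.35), *Obp99a* (-3.31) and *spz6*, a Spätzle family ligand gene (-3.03). Of these, *CG13362*, *nw* and *Obp99a* were among the leading genes of unnamed cluster 7, with 309 and 12 cells at stages 14 and 16. *nw*, *wbl* and *Obp99a* were among those of unnamed cluster 17, with 211 and 7 cells. Fewer such cells and lower levels per cell were not separated in these ratios. *CG9184* stood at 9365 and 1311 CPM (-2.84, -2.85 to -2.82). *fon*, a clotting factor gene, stood at 6.77 and 155 CPM (4.52). The median of all genes was -0.22, and scaling by median-of-ratios moved it by 0.17.

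**Figure D2:**
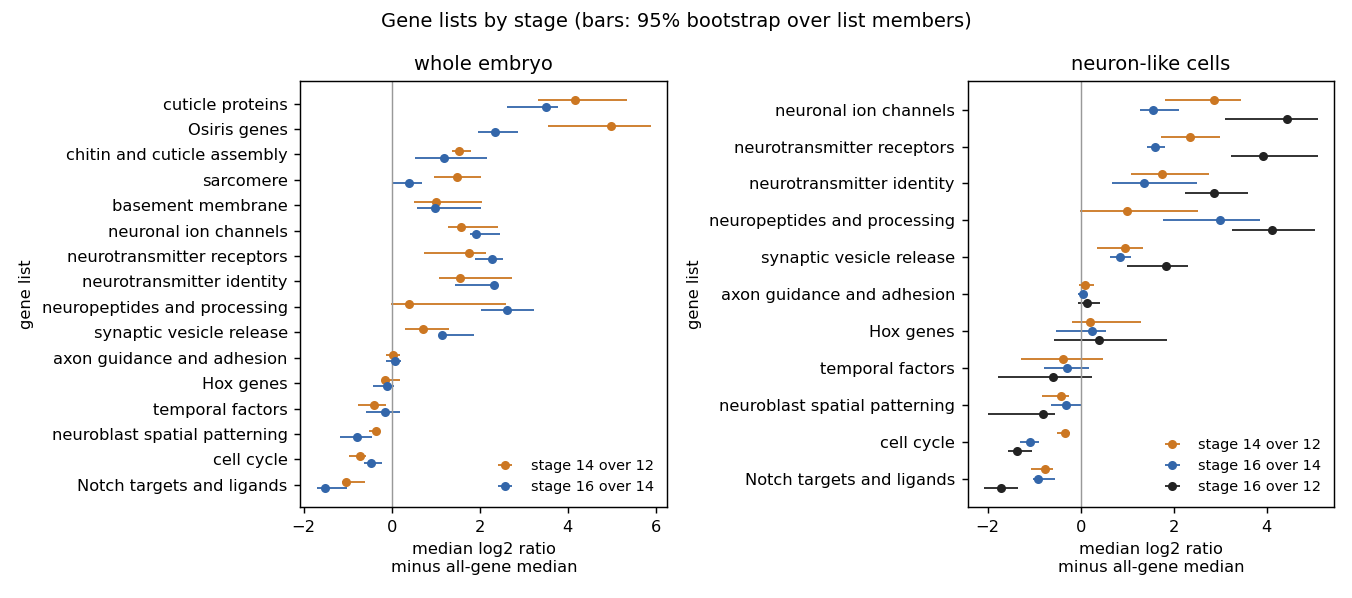
Median log2 ratio of each gene list minus the median of all genes (x axis, log2 scale) in the whole embryo and in neuron-like cells, by comparison of stages (colours); lines are 95% bootstrap intervals over list members. In neuron-like cells ion channels stood at 4.43 and Notch targets and ligands at -1.72 for stage 16 over stage 12.

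The hormone-response gene *ftz-f1*, which encodes a nuclear receptor induced after pulses of the steroid ecdysone, was higher at stage 16 than at stage 14 in every class with at least 200 cells at both stages. In the whole embryo *ftz-f1* (FBgn0001078, chromosome 3L, 18750607 to 18801309) stood at 3.91, 121 and 1191 CPM at stages 12, 14 and 16. At stage 16 its level was 1875 CPM in hemocyte-like cells, 1691 in epidermis-like cells, 1209 in midgut-like cells, 1145 in fat body-like cells, 663 in somatic muscle-like cells, 581 in glia-like cells and 285 in neuron-like cells. Markers of other tissues were also higher in these classes, with Osiris medians of 6.61 in hemocyte-like and 5.84 in neuron-like cells for stage 16 over stage 12, and free RNA was not separated from expression. *Hr4*, another ecdysone-response nuclear receptor (FBgn0264562, chromosome X, 1941940 to 2007956), stood at 622, 806 and 258 CPM, with a log2 ratio of -1.65 (-1.68 to -1.61) between stages 14 and 16, and *Hr39* at -1.70. *Cyp18a1*, which inactivates ecdysone, was at 56.6 CPM at stage 14 and 159 at stage 16. In neuron-like cells *Hr4* stood at 773 CPM at stage 12 and 137 at stage 16, and *Eip75B* at 354 and 77.9. In somatic muscle-like cells *Hr4* stood at 422 and 509 CPM at the same stages. These values of *Hr4* by class were chosen after the values were seen. The median of the ecdysone pathway list between stages 14 and 16 in the whole embryo was 0.19, with 5 of 15 members at least 2-fold higher and 4 at least 2-fold lower, and it was -0.24 when only members with at least 20 CPM were used.

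Neuroblast-like cells were compared between stages 14 and 12, since stage 16 had 135 of them, too few for the minimum of 200. They were cells of clusters 6 and 28, with 66.6% in cluster 6 at stage 12 and 74.7% at stage 14, and a median of 2892 and 2480 UMIs. The neuronal RNA-binding protein gene *elav* stood at 3049 CPM in these cells at stage 12, against 3357 in neuron-like cells. Unnamed cluster 3, with 368 cells at stage 12 and 209 at stage 14, was not part of the class. Its leading genes included the neuroblast marker *mira* and the cell cycle genes *tum*, *polo* and *fzy*. Among the temporal factors, which neuroblasts express in sequence, the early factor *Kr* (FBgn0001325, chromosome 2R, 25226611 to 25231394) stood at 78.3 CPM at stage 12 and 54.1 at stage 14 (log2 ratio -0.54, -0.90 to -0.19). *svp*, a nuclear receptor gene that acts as a switching factor (FBgn0003651, chromosome 3R, 12258737 to 12302785), stood at 122 and 199 CPM (0.70, 0.49 to 0.91), and *nub* at 87.8 and 64.0. The list had a median of -0.36 (bootstrap interval over its 9 members -0.53 to 0.06). Without cluster 3, cell cycle genes stayed close between the stages, with a median of -0.30 and none of 37 past 2-fold. Synaptic vesicle release genes had a median of 0.64 (6 of 19 at least 2-fold higher), which was 0.26 with barcode suffix 2. Sarcomere genes, which mark another tissue, had a median of 1.41 in the same cells (12 of 20 at least 2-fold higher), and Osiris genes 4.44. The genes with the highest ratios were *lncRNA:CR43283* (2.85, 2.68 to 3.02), *CG9184* (1.76), *CG31813* (1.72), *fabp*, a fatty acid binding protein gene (1.60), and *Pex7*, a peroxisomal import receptor gene (1.34). Those with the lowest were *nw* (-2.05), *ab* (-1.92), *Ama* (-1.42), *Cys* (-1.32) and *lncRNA:CR43432* (-1.08).

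The share of neuroblast-like cells with a UMI was compared after each cell was thinned to 1000 UMIs, which left out 100, 87 and 30 cells with fewer UMIs at stages 12, 14 and 16. *Kr* was detected in 6.33% (4.42 to 8.74), 1.81% (0.591 to 4.18) and 1.90% (0.232 to 6.71) of cells, and *svp* in 5.77% (3.96 to 8.09), 10.5% (7.15 to 14.7) and 16.2% (9.72 to 24.7). *cas*, a late temporal factor gene, was detected in 29.2% (25.4 to 33.3), 33.0% (27.5 to 38.9) and 18.1% (11.3 to 26.8), and *grh*, the last of the series, in 25.3% (21.7 to 29.2), 30.4% (25.1 to 36.2) and 34.3% (25.3 to 44.2). *hb*, the earliest, was detected in 0.559% at stage 12 and in 0 of 276 cells at stage 14, which allows up to 1.09% of cells with a UMI. Without thinning the shares were 19.5%, 10.5% and 3.70% for *Kr*, 10.8%, 20.1% and 25.9% for *svp*, 41.8%, 39.9% and 25.9% for *cas* and 42.5%, 44.6% and 48.9% for *grh*. Hemocyte-like cells, taken as background with a median of 6950 UMIs at stage 12, 5074 at stage 14 and 4624 at stage 16 against 2892, 2480 and 1796 in neuroblast-like cells, gave 0.754%, 0.379% and 0% for *Kr*, 1.26%, 1.14% and 0.397% for *svp*, 1.51%, 1.14% and 0.397% for *cas* and 5.28%, 3.22% and 1.79% for *grh* after thinning. The difference in the share of *Kr* between stages 14 and 12 was -4.52 percentage points, which was -0.905 without the 5% of cells with the highest Scrublet scores and -0.87 with at least 600 genes and at most 5% mitochondrial UMIs. For *svp* the difference was 4.73 percentage points, and 9.75 when cells were thinned to 2000 UMIs. The shares of *cas* and *grh* at stages 12 and 14 were not distinguishable at this depth. The differences turned for *grh*, to -1.98 percentage points with barcode suffix 2, and for *cas*, from 3.73 to -1.81 without thinning.

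**Figure D3:**
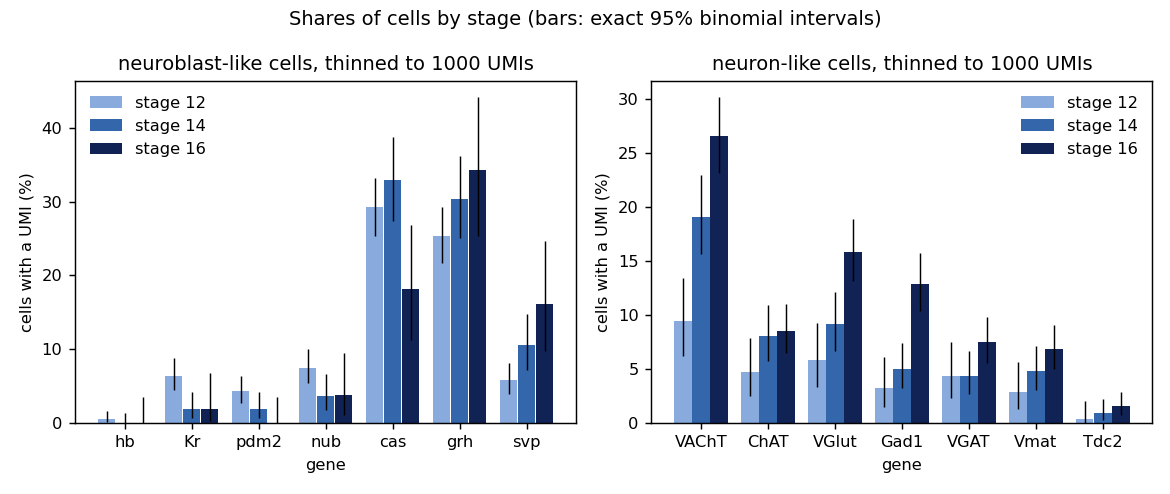
Share of cells with at least 1 UMI (%, y axis) of temporal factor genes in neuroblast-like cells and of neurotransmitter genes in neuron-like cells, each cell thinned to 1000 UMIs, at stages 12, 14 and 16; lines are exact 95% binomial intervals. *svp* stood at 5.77%, 10.5% and 16.2%, and *VAChT* at 9.39%, 19.1% and 26.6%.

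Neuron-like cells of stage 16 held far more transcripts for electrical excitability, transmitter reception and neuropeptides than those of stage 12. Of 23 measured ion channel genes, 21 were at least 2-fold higher at stage 16, with a median log2 ratio of 4.39 (bootstrap interval over members 3.06 to 5.06). *para* stood at 4.79 and 768 CPM (7.32, 6.68 to 8.06), the potassium channel gene *Sh* at 3.28 and 495 (7.24, 6.46 to 8.15), *slo* at 6.30 and 625 and *SK* at 4.54 and 377. Of 23 neurotransmitter receptors, 21 were at least 2-fold higher (median 3.88), with *Rdl* at 7.56 and 1063 CPM (7.14, 6.62 to 7.70) and the acetylcholine receptor gene *nAChRalpha6* at 6.30 and 612. All 14 neurotransmitter identity genes were at least 2-fold higher (median 2.82), among them *Gad1* at 21.4 and 183 CPM (3.09, 2.77 to 3.43) and *ple*, tyrosine hydroxylase, at 1.26 and 20.3. Of 24 neuropeptide and processing genes, 22 were at least 2-fold higher (median 4.07). The peptide genes *AstA*, *AstC*, *Ms* and *SIFa* had no UMI at stage 12 and were at least 40.9-fold, 29.2-fold, 68.3-fold and 74.3-fold higher at stage 16, where 14, 15, 6 and 4 cells held them. Synaptic vesicle release genes had a median of 1.80 (15 of 23 at least 2-fold higher), with *Rim* at 4.56, *Snap25* at 4.36, *Syn* at 3.83 and *Syt1* at 3.59. *para*, *Rdl*, *Gad1* and *Syt1* were also among the marker genes that named the class.

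Cell cycle genes and Notch targets and ligands were lower in neuron-like cells of stage 16 than in those of stage 12. Of 37 cell cycle genes, 28 were at least 2-fold lower (median -1.41), with the mitotic cyclin gene *CycB* at 112 and 18.9 CPM (-2.57, -2.90 to -2.25). Of 15 Notch targets and ligands, 14 were at least 2-fold lower (median -1.76), with *Tom* at 244 and 14.8 CPM (-4.04, -4.40 to -3.70). The temporal factors had a median of -0.64 (bootstrap interval -1.81 to 0.21), with *hb* at 59.7 and 13.2 CPM (-2.18), *pdm2* at -1.84 and *cas* at -1.23. The Hox gene *Ubx*, which gives segments their identity, stood at 1097 and 666 CPM (-0.72, -0.78 to -0.65). The genes with the highest ratios were *Cbp53E*, a calcium-binding protein gene, at 1 and 1128 UMIs (9.79, 7.30 to 15.09), *TwdlF* (9.77, 7.29 to 15.08), *Phk-3* (8.95), *CG9083*, at least 290-fold higher, and *CG14075*, at least 607-fold higher with 63.1% of its UMIs in 1 cell. Below *Tom*, the lowest were *CG8407* (-3.63), *CG7372* (-2.93), *insb* (-2.76) and *lncRNA:CR43432* (-2.71). Markers of other tissues were also higher in these cells at stage 16, with medians of 2.41 for sarcomere genes, 5.09 for cuticle proteins and 5.84 for Osiris genes. Cluster 8 held 97.9% of neuron-like cells at stage 12, and cluster 23 held 74.3% at stage 16, so the classes compared were largely different clusters.

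Transmitter genes were detected in a larger share of neuron-like cells at stage 16 than at stage 12. After thinning to 1000 UMIs, *VAChT*, the vesicular acetylcholine transporter gene, was detected in 9.39% (6.22 to 13.5) of cells at stage 12, 19.1% (15.6 to 23.0) at stage 14 and 26.6% (23.2 to 30.1) at stage 16. *VGlut* was detected in 5.78% (3.34 to 9.21), 9.11% (6.65 to 12.1) and 15.8% (13.1 to 18.9), and *Gad1* in 3.25% (1.496 to 6.08), 4.99% (3.19 to 7.39) and 12.9% (10.4 to 15.7). Thinning left out 105, 315 and 367 neuron-like cells. Between stages 12 and 16 the difference was 17.2 percentage points for *VAChT* and 9.64 for *Gad1*, which were 28.9 and 15.7 when cells were thinned to 2000 UMIs, and 10.1 for *VGlut*, which was 17.1 with at least 600 genes and at most 5% mitochondrial UMIs. Without thinning the shares were 23.6%, 32.0% and 40.8% for *VAChT*, 12.3%, 14.7% and 20.1% for *VGlut* and 8.64%, 8.63% and 17.7% for *Gad1*. Somatic muscle-like cells, taken as background with a median of 5803, 5065 and 847 UMIs against 2815, 1419 and 1760 in neuron-like cells, gave 0%, 0.563% and 1.49% for *VAChT*, 0%, 0.281% and 0% for *VGlut* and 0% at each stage for *Gad1*. For *Gad1*, 0 of 269 such cells at stage 16 allows up to 1.12% of cells with a UMI.

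Glia-like cells, all from cluster 18, were compared between stages 16 and 14. The glutamate transporter gene *Eaat1* was higher at stage 16, and *gcm*, the transcription factor gene that starts glial fate (FBgn0014179, chromosome 2L, 9579498 to 9581745), was lower, at 511 CPM at stage 14 and 40.3 at stage 16 (log2 ratio -3.67, -4.21 to -3.17). *Obp44a*, an odorant binding protein gene (FBgn0033268, chromosome 2R, 8134170 to 8135315), stood at 10.4 and 1356 CPM (7.03, 6.19 to 8.04) and *Eaat1* at 16.0 and 403 (4.65, 3.95 to 5.45). *CG6356* (3.797), *Mp*, a collagen gene (3.55), and *CG9083* (3.55) followed. The septate junction and blood-brain barrier list had a median of 0.12, with the junction scaffold gene *vari* at 2.94 and the sodium pump subunit gene *nrv2* at 1.52, and its direction turned with cells weighted equally and at Leiden resolution 0.75. Basement membrane genes had a median of 0.72 (0.91 relative), or 0.42 with cells weighted equally, and *vkg* stood at 3.47. Of 35 cell cycle genes, 26 were at least 2-fold lower (median -1.61, -1.41 relative, and -1.02 with cells weighted equally), among them *aurB* at 32 and 2 UMIs (-3.67, -6.78 to -1.70). Of 15 Notch targets and ligands, 12 were at least 2-fold lower (median -1.67, -1.48 relative), with *Tom* at 405 and 21.3 CPM. Low ratios were also found for *lncRNA:CR43432* (-3.67), *Obp99a* (-3.57) and *CG9184* (-3.41). *Eip75B* stood at 347 and 71.0 CPM. The median of all genes in this class was -0.19, sarcomere genes had a median of 0.45, cuticle proteins 2.15 and Osiris genes 1.496, and median depth was 1801 UMIs at stage 14 and 1510 at stage 16.

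Somatic muscle-like cells of stage 16 held more sarcomere transcripts and fewer transcripts of myoblast fusion and cell division than those of stage 12. Of 24 sarcomere genes, 22 were at least 2-fold higher (median log2 ratio 3.06, 3.61 relative to all genes), a list that shares members with the markers that named the class. The 5% of cells with the most sarcomere UMIs held 23.8% of the sarcomere UMIs of the class at stage 12 and 54.6% at stage 16. *Mhc* (FBgn0264695, chromosome 2L, 16766566 to 16788766) stood at 268 and 5259 CPM (4.30, 4.21 to 4.39), *Prm* at 26.6 and 1326 (5.64, 5.37 to 5.92), the Z-disc gene *Zasp52* at 2.80 and 121 and *Mlp84B* at 67.3 and 1023. The glutamate receptor genes of the neuromuscular junction *GluRIIE*, *GluRIIC* and *GluRIIA* had log2 ratios of 3.98, 2.84 and 2.46, and *GluRIIB* had -1.23, in a list with a median of 0.67. Basement membrane genes had a median of 2.12 (bootstrap interval -0.12 to 3.62). The median of all genes in this class was -0.55. Myoblast fusion genes had a median of -1.13 (7 of 12 at least 2-fold lower), or -0.69 with median-of-ratios scaling. The fusion receptor genes *rst* and *kirre* stood at 354 and 39.2 CPM (-3.17, -3.53 to -2.83) and at 433 and 73.1 (-2.57). Cell cycle genes had a median of -1.86 (17 of 27 at least 2-fold lower), with *stg*, the Cdc25 phosphatase gene, at 419 and 33.9 CPM. *jhamt* (FBgn0028841, chromosome 2L, 16365903 to 16367039) stood at 4847 and 3 UMIs (-9.45, -11.73 to -7.90), *Con*, an adhesion gene, had -3.56 and *bnb* -3.21. *ftz-f1* stood at 3 and 1234 UMIs (9.89, 8.34 to 12.17). The epidermal genes *CG2962*, *CG9083*, *Osi15* and *Osi14* had no UMI at stage 12 and were at least 330-fold, 477-fold, 287-fold and 341-fold higher, beside medians of 7.38 for Osiris genes and 4.35 for cuticle proteins. The cells came mainly from clusters 2 and 0 at stage 12 and from cluster 25 (71.6%) and cluster 39 (21.1%) at stage 16, where median depth was 847 UMIs against 5803. Unnamed cluster 5, led by *jhamt* and with *sns* and *lmd* among its leading genes, was not part of the class. It held 1172 cells at stage 12 and 1 at stage 16. The stage 12 values of the fusion genes and *jhamt* therefore cover only part of the cells with these transcripts. At Leiden resolution 0.75 the median of the cell cycle list was 0.48 and that of sarcomere genes 1.94, and the fusion genes *hbs* and *rols* had 0.12 and 1.16. With each stage clustered on its own the medians were -2.64 for cell cycle, 3.96 for sarcomere and -3.11 for myoblast fusion genes.

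Hemocyte-like cells of stage 16 held more transcripts of the basement membrane they secrete and fewer Notch-response transcripts than those of stage 12. Of 11 basement membrane genes, 10 were at least 2-fold higher (median log2 ratio 1.46, 1.97 relative). The list members *Pxn* and *Ppn* were also among the markers that named the class. Both, with *Col4a1* and *vkg*, were among the leading genes of cluster 38, which held most of the class at stage 16. *Col4a1* (FBgn0000299, chromosome 2L, 5029609 to 5037279) stood at 2991 and 23140 CPM (2.95, 2.92 to 2.98), *vkg* at 907 and 7107, *SPARC*, a collagen-binding protein gene, had 2.83, and *trol* stood at 45.1 and 1151 CPM (4.67, 4.43 to 4.93). Of 18 Notch targets and ligands, 15 were at least 2-fold lower (median -3.63, -3.12 relative, and -4.53 with each stage clustered on its own), among them *E(spl)m4-BFM* (-4.14), *E(spl)m7-HLH* (-3.88) and *Tom* (-3.93). Of 35 cell cycle genes, 27 were at least 2-fold lower (median -1.91, -1.40 relative), with *fzr* at 82.8 and 15.1 CPM. Heat shock genes had a median of -2.30 (5 of 9 at least 2-fold lower, bootstrap interval -2.84 to 0.49), with *Hsp27* at 68.6 and 5.38 CPM. *ftz-f1* had the highest ratio (7.11, 6.68 to 7.59), and *slbo*, a C/EBP transcription factor gene, had 6.03, *jtb* 5.43, *Osi6* 7.07 and *Osi7* 6.55. *lncRNA:CR43432* had the lowest, at 1345 and 45.9 CPM (-4.87), and *CG18754* had -3.92. Sarcomere genes had a median of 2.09 (2.82 with cells weighted equally), Osiris genes 6.61 and cuticle proteins 4.93 in the same cells. Cluster 20 held 93.2% of the class at stage 12 and cluster 38 held 91.5% at stage 16, and the median of all genes was -0.51.

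Epidermis-like cells were compared between stages 16 and 14, the stages with at least 200 of them. Cuticle protein genes were higher at stage 16 for 49 of 54 members by at least 2-fold (median log2 ratio 3.75, 4.27 relative, and 3.12 with cells weighted equally). *Lcp65Ag2* had 6.97 (6.21 to 7.84), *TwdlB* 6.09 (5.73 to 6.46) and *TwdlL* 5.14, and *CG9757* and *CG31626* had 9.01 and 5.47. *Lcp65Ac* had no UMI at stage 14 and was at least 141-fold higher at stage 16, in 4 cells. Osiris genes had a median of 1.44 (12 of 15 at least 2-fold higher), and chitin and cuticle assembly genes 1.17 (11 of 21 higher and 3 lower), with *obst-E* at 24.4 and 464 CPM, the pigmentation gene *y* at 4.16 and *Gasp* at 554 and 3910. *obst-E* and *y* were also among the markers that named the class. Segment polarity genes had a median of -1.44 (7 of 11 at least 2-fold lower), with *en* at 54.1 and 4.26 CPM (-3.67, -4.29 to -3.10) and *hh* at -1.96. Septate junction genes had a median of -0.93 (5 of 17 at least 2-fold lower), or -0.41 relative to all genes. The genes with the lowest ratios were *CG13983* (-5.73), *CG17047* (-5.39), *Tom* (-4.48), the transcription factor gene *vri* (-4.44) and *lncRNA:CR43432* (-4.40). *CG17047* had -3.74 without barcodes over 50000 UMIs, and 64.2% of its stage 14 UMIs came from 1 cell. Sarcomere genes had a median of 1.37 in the same cells, cluster 16 held 87.2% of the class at stage 14 and cluster 41 held 82.5% at stage 16, and the median of all genes was -0.53, which median-of-ratios scaling moved by 0.56. Cluster 42, with *TwdlF*, *TwdlW*, *TwdlM* and *Cpr65Ea* among its leading genes, held 2.31% and 10.8% of the class. Its cells had a median depth of 14.5 times the median of their stage, against 0.71 in cluster 41. At stage 16, 22 of its 147 cells had over 50000 UMIs. Summed UMIs therefore weight cluster 42 above its share of cells.

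**Figure D4:**
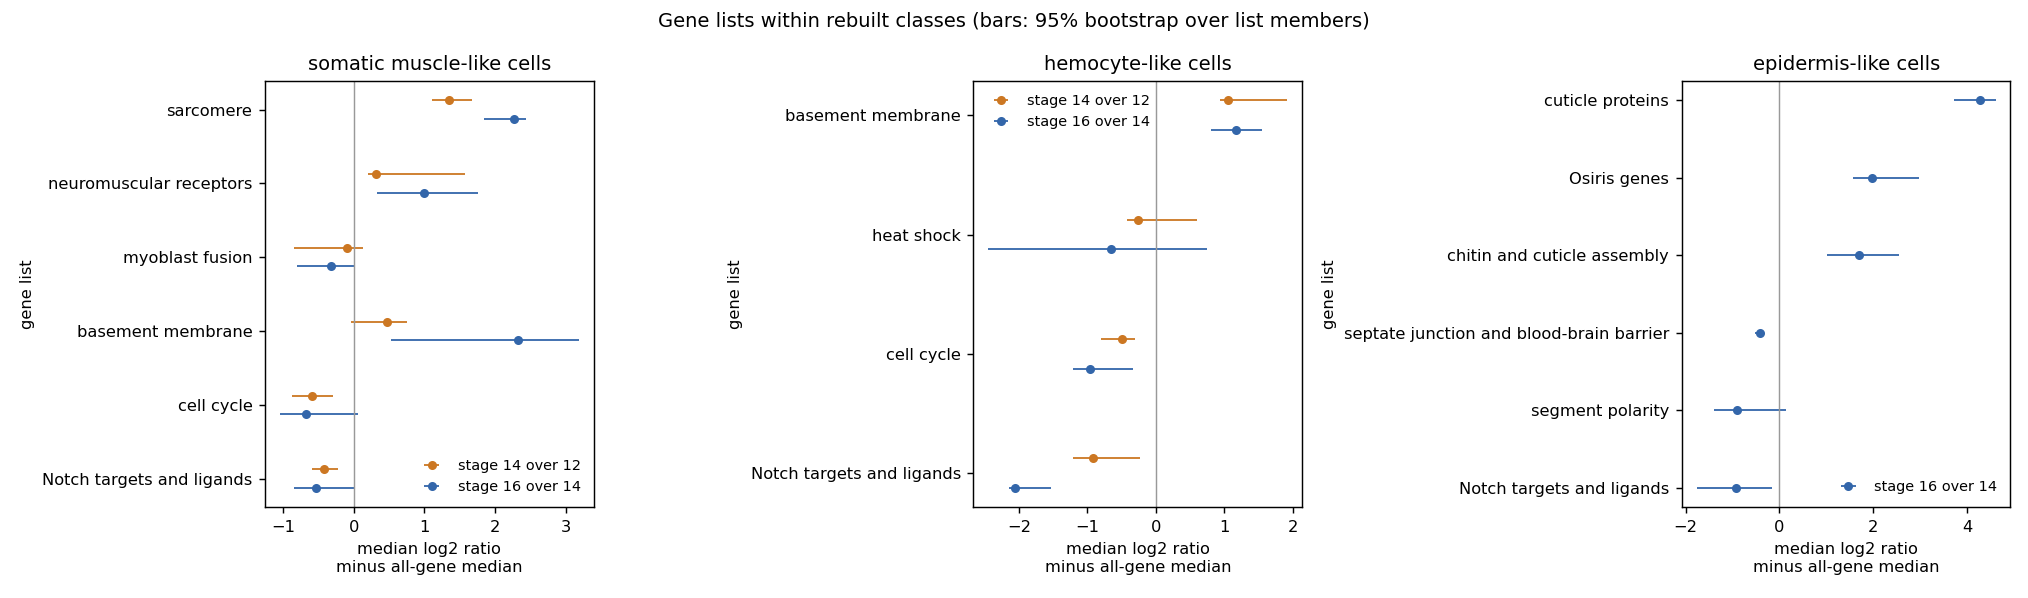
Median log2 ratio of each gene list minus the median of all genes (x axis, log2 scale) in somatic muscle-like, hemocyte-like and epidermis-like cells, by comparison of stages (colours); lines are 95% bootstrap intervals over list members. In epidermis-like cells cuticle proteins stood at 4.27 for stage 16 over stage 14.

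Fat body-like cells of stage 16 were also compared with those of stage 14. *fon* stood at 5.29 and 374 CPM (log2 ratio 6.14, 5.64 to 6.68) and *ftz-f1* at 26.2 and 1145 (5.45, 5.22 to 5.69). With cells weighted equally the ratios of *fon* and *ftz-f1* were 4.63 and 3.95. *TwdlF*, *CG9083* and *CG2962* had 5.17, 5.12 and 4.89. Markers of other tissues were also higher in these cells at stage 16, with medians of 3.74 for Osiris genes, 4.03 for cuticle proteins and 2.06 for sarcomere genes. *CG10591* stood at 212 and 24.0 CPM (-3.14, -3.84 to -2.52), and *CG18754* had -1.91, *Eip71CD* -1.70, *CG4825* -1.33 and *lncRNA:CR43432* -1.29. With cells weighted equally these were -2.44, -2.61, -2.94, -1.91 and -2.98, and 41.9% of the stage 14 UMIs of *CG10591* came from 1 cell. Cluster 11 held 78.1% of these cells at stage 14 and cluster 9 held 81.6% at stage 16, and median depth was 6275 and 946 UMIs. Unnamed cluster 12, whose highest marker score was for fat body, was not part of the class and held 68 cells at stage 14 and 389 at stage 16, the latter with a median of 9646 UMIs, so the values for stage 16 cover only part of the fat body-like cells.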

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

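The reporter and driver transcripts stood out because they are features of the matrices that no comparison used, and the tests of the *tra* pattern were chosen only after its values were seen. RedstingerNLS had 5112 UMIs at stage 12, 4819 at stage 14 and 3664 at stage 16, and Gal4 had 2619, 3519 and 1073. Cells with at least 3 UMIs of both numbered 26, 19 and 10, against 254, 255 and 179 for RedstingerNLS and 201, 217 and 80 for Gal4. Most cells that passed this threshold for 1 of the transcripts thus did not pass it for the other. The overlap was still a larger part of the Gal4 cells than the 3.12%, 2.40% and 2.53% of all kept cells that passed for RedstingerNLS. Detection at this threshold depends on depth, so the overlap cannot say how far the 2 transcripts were made in the same cells. Gal4 cells lay most often in cluster 7 at stage 12 (32.8%), fat body-like cells at stage 14 (32.3%) and cluster 12 at stage 16 (27.5%). Of all *tra* UMIs, 90.2%, 86.5% and 91.0% lay in cells with a reporter UMI. Reads of the reporter transcript may have been counted as *tra*: the extra *tra* UMIs per reporter UMI differed between classes by at most 1.39-fold, which fits that explanation. Cells with at least 3 reporter UMIs held at least 42.4 times the *tra* UMIs of cells matched by cluster, but this excess follows from the pattern itself. Every class measured had extra *tra*, at 2.65 to 3.68 UMIs per reporter UMI at stage 12, 2.71 to 3.04 at stage 14 and 2.25 to 2.61 at stage 16. Epidermis-, glia- and neuron-like cells were among them at each stage, which argues against a single cell type. Cells of several classes that make both transcripts stayed open, as did stage, which was not tested.

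Sarcomere genes were higher at stage 14 than at stage 12 in neuroblast-like cells, with a list median of 1.41, and of the tests below only the one with classes kept was chosen after the result was seen. Free RNA from muscle could account for it: the median deviation of the genes' proportions from the whole embryo at stage 14 was 0.636 in neuroblast-like, 0.649 in neuron-like and 0.991 in glia-like cells, between the bounds of 0.5 for and 1 against, so free RNA and expression in the cells cannot be told apart. At stage 12, where the level to be explained was lower, the deviations were 1.18, 1.79 and 1.72. Without the 5% highest Scrublet scores the list median was higher, at 1.68, or 1.58 with classes kept (falls of -0.28 and -0.17), which is against droplets with a muscle cell and a neuroblast, but these stayed open because Scrublet called only 1, 0 and 2 doublets, so its scores may not find them, and because 41.5% and 33.0% of the sarcomere UMIs of the class lay in its top 5% of cells at stages 12 and 14. A real difference of stage stayed untested.

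Barcodes with over 50000 UMIs held 15.3%, 18.6% and 33.7% of all UMIs at stages 12, 14 and 16, and both tests of them were chosen before their results were seen. Droplets with several cells of different classes might make such barcodes. The test used those in named clusters with enough other cells to compare, 59 of 95, 102 of 118 and 64 of 128 of them. Their share of off-class markers was at most 1.02 times that of other cells of the same clusters. That share was already 63.0%, 67.5% and 66.3% in those other cells, which can hide an admixture, so mixing stayed open. A few genes taking most UMIs might make them too, but the share of their 10 highest genes was at most 1.02 times that of other cells, which speaks against this. Differences in cell size stayed untested.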

How the results depend on the processing

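Both barcode suffixes together, the removal of the 5% of cells with the highest Scrublet scores, the omission of barcodes over 50000 UMIs, and the use of cells with at least 1000 UMIs were chosen after seeing the data; the other alternatives were set before. For the counts below, the bootstrap intervals of list medians were drawn again and can differ from those printed above. For example, the temporal factors in neuroblast-like cells had -0.53 to 0.37 here. Over 72 results and 18 settings there were 794 values, of which 692 stayed within the interval of the value reported, 91 lay outside it and 11 turned direction. Of those that stayed within it, 8 also changed sign: the *cas* difference (-1.81 percentage points without thinning and -0.679 without the highest Scrublet scores), the *grh* difference (-0.540 at Leiden resolution 3), and ecdysone medians in the whole embryo (-0.24 with a floor of 20 CPM and -0.17 under the strict filter), somatic muscle (-0.55 with a floor of 20 CPM and -0.0579 with suffix 2) and neuron (-0.0450 with suffix 2). For 327 named-gene ratios and 13 settings there were 3365 values, of which 2544 stayed within it, 818 lay outside it and 3 turned. No paired analysis was possible because each stage was 1 pooled matrix, although lane numbers recur in the labels. The cause of the values below was not tested in any of these groups. Share ratios are log2 of stage 16 over stage 12, and list medians are log2 ratios.

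With both suffixes the share ratio was 1.87 for epidermis, -2.44 for neuroblast and -0.30 for somatic muscle, the last a turn. With suffix 2 alone it was 0.48 for epidermis, 1.81 for neuron and 1.31 for somatic muscle, and the *grh* share difference in neuroblast-like cells turned to -1.98 percentage points. With suffix 2 the neuroblast medians were 1.95 for sarcomere and 0.26 for synaptic vesicle release genes, and the epidermis septate junction median was -1.19.

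Without the 5% highest Scrublet scores the share ratio was 2.36 for epidermis and 0.55 for somatic muscle, the *Kr* share difference was -0.905 percentage points, and the hemocyte medians were -1.49 for cell cycle and 2.75 for sarcomere genes. With doublets kept the share ratio was 2.51 for epidermis, 1.81 for midgut and 1.80 for neuron. This setting added back only the 1, 0 and 2 called doublets and clustered the cells again. These moves therefore came with a repeated clustering of nearly the same cells, and the intervals on shares do not cover them.

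At Leiden resolution 0.75 the share ratio was 1.76 for epidermis, 0.66 for neuron, 3.12 for somatic muscle and, turned, -0.0728 for midgut. The somatic muscle median was 1.94 for sarcomere genes and, turned, 0.48 for cell cycle genes, as were the ratios of *CycA* (0.0482), *hbs* (0.12) and *rols* (1.16), and the glia septate junction median turned to -0.0200. At resolution 3 the share ratio was 3.87 for epidermis, 2.63 for neuron and 1.57 for somatic muscle.

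With each stage clustered on its own the share ratio turned to -0.46 for epidermis and -1.47 for somatic muscle, and was 0.48 for glia, 0.88 for midgut and -2.35 for neuroblast. Cell cycle medians were -1.14 in glia, -0.0557 in neuroblast, -1.72 in neuron and -2.64 in somatic muscle. The somatic muscle medians were -3.11 for myoblast fusion and 3.96 for sarcomere genes, the hemocyte Notch median was -4.53 and the epidermis septate junction median -1.18. With class by highest marker score the share ratio was 1.96 for epidermis, 1.28 for midgut, -1.65 for neuroblast, 2.46 for somatic muscle and, turned, -0.43 for glia.

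With at least 600 genes and at most 5% mitochondrial UMIs the share ratio was 7.43 for epidermis, 0.18 for glia, 2.06 for hemocyte, 0.0243 for midgut, -1.15 for neuroblast, 2.68 for neuron and 0.12 for somatic muscle. Share differences in percentage points were -0.87 for *Kr* (stage 14 minus 12), 11.8 for *VAChT* and 17.1 for *VGlut* (stage 16 minus 12). Whole-embryo medians were 1.75 for chitin and cuticle assembly (stage 14 over 12), 1.32 for ion channels and 0.68 for synaptic vesicle release (stage 16 over 14). With no filter on cells the share ratio was 2.90 for epidermis, 0.39 for hemocyte, 1.78 for midgut, 1.94 for neuron and, turned, -0.19 for somatic muscle. With cells of at least 1000 UMIs it was 1.33 for glia, 1.19 for hemocyte, 0.57 for midgut, -1.51 for neuroblast, 2.07 for neuron and, turned, -0.065 for somatic muscle.

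Without barcodes over 50000 UMIs the whole-embryo medians were 3.57 for cuticle proteins (stage 16 over 14), and 2.02 and 2.33 for neurotransmitter receptors (stage 14 over 12, and 16 over 14), and the epidermis septate junction median was -0.82. With cells weighted equally the whole-embryo medians were 2.95 for cuticle proteins, 1.14 for chitin and cuticle assembly and 2.08 for receptors (stage 14 over 12), and -1.21 for Notch (stage 16 over 14). The cell cycle medians were -1.02 in glia, -1.44 in hemocyte and -0.17 in neuroblast. Other medians were 0.42 for basement membrane and, turned, -0.20 for septate junction genes in glia, 3.12 for cuticle proteins and -0.86 for septate junction genes in epidermis, and 2.82 for sarcomere genes in hemocyte.

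With median-of-ratios scaling the medians were 2.27 for neurotransmitter identity in the whole embryo (stage 16 over 14), 4.31 for cuticle proteins and -0.36 for septate junction genes in epidermis, 3.51 for sarcomere and -0.69 for myoblast fusion genes in somatic muscle, and -1.48 for cell cycle and 2.55 for sarcomere genes in hemocyte. With a list floor of 20 CPM they were 6.22 for cuticle proteins (stage 14 over 12), 0.72 for neuropeptides and 2.34 for receptors (stage 16 over 14) in the whole embryo, and -1.66 for cell cycle genes in hemocyte. With totals without ribosomal and mitochondrial genes all 58 results stayed.

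Without thinning the share difference in neuroblast-like cells was -9.00 percentage points for *Kr* and 9.28 for *svp*. Thinned to 2000 UMIs it was 9.75 for *svp*, and in neuron-like cells 28.9 for *VAChT* and 15.7 for *Gad1*.

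Most within-class medians had no value under the strict filter, for too few cells, and no filter was not run within classes. The highest marker score and the minimum of 1000 UMIs were run for class shares only, and suffix 1 alone was the setting used throughout. Median depth of 4524 UMIs at stage 12 against 1018 at stage 16 limits every class share and every detection of low transcripts at stage 16.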

Other observations

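Cells with at least 3 reporter UMIs numbered 254 at stage 12, 255 at stage 14 and 179 at stage 16. Of these, 15, 10 and 3 were neuroblast-like, 35, 41 and 60 neuron-like and 19, 48 and 31 glia-like. A further 5, 33 and 35 were epidermis-like, 7, 32 and 1 fat body-like and 12, 16 and 6 sensory organ-like. Unnamed cluster 7 held 94, 34 and 2, or 37.0% at stage 12. Of all cells with at least 3 reporter UMIs, 253, 254 and 176 were compared with cells matched by cluster for genes that pattern the neuroectoderm, a comparison chosen after the data were seen. The paired-domain gene *gsb* was 4.22-fold (3.97 to 4.48) the matched level at stage 12, 3.31-fold at stage 14 and 3.97-fold at stage 16, and its neighbour *gsb-n* was 4.92-fold, 4.21-fold and 3.37-fold. The signal gene *wg* was 4.04-fold, 2.83-fold and 2.10-fold, and the forkhead gene *slp1* 3.39-fold, 3.25-fold and 2.29-fold. *slp2* was 2.92-fold, 2.61-fold and 2.37-fold, and *oc* 1.42-fold, 1.51-fold and 1.13-fold. Other members of the same list were lower at each stage, with *ems* at 0.414-fold, 0.654-fold and 0.633-fold, *mirr* at 0.768-fold, 0.765-fold and 0.710-fold and *Dr* at 0.779-fold, 0.841-fold and 0.703-fold. Among genes expressed in the posterior of each segment, *hh* was 0.475-fold, 0.425-fold and 0.781-fold, *en* 0.944-fold, 0.804-fold and 1.86-fold, and *inv* 0.917-fold, 0.907-fold and 1.77-fold. Among Hox genes, *Scr* was 0.417-fold, 0.315-fold and 1.04-fold, *Dfd* 0.335-fold, 1.22-fold and 1.18-fold, and *Abd-B* 0.994-fold, 0.568-fold and 1.39-fold. *lab* was 0.714-fold, 0.626-fold and 0.443-fold, and *pb* 0.932-fold, 0.801-fold and 1.43-fold. *Antp* was 1.30-fold, 1.71-fold and 1.397-fold, *abd-A* 1.54-fold, 1.399-fold and 1.295-fold, and *Ubx* 1.80-fold, 1.15-fold and 1.28-fold.

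Cluster 26, named germ cell, held many transcripts that mothers load into eggs. *wisp*, a poly(A) polymerase gene, stood at stages 12, 14 and 16 at 488, 780.2 and 1217 CPM, against 2.57, 1.82 and 1.68 in other cells. *bcd*, the anterior morphogen gene, stood at 215, 154 and 363 CPM and stood below 1 CPM in other cells. *osk* stood at 113, 221 and 44.6 CPM and *dhd* at 658, 729 and 27.9, with only 8 and 5 UMIs at stage 16. The germ cell gene *vas* stood at 132, 48.4 and 22.3 CPM against 9.77, 9.24 and 3.24, with UMIs in 9, 12 and 3 of these cells. *zpg* stood at 412, 218 and 212 CPM against 4.26, 3.49 and 1.03, and *nos* at 114.9, 39.3 and 145 against 0.170, 0.2597 and 0.0541. UMIs of *zpg* were found in 22, 17 and 8 cells of the cluster, and those of *nos* in 14, 6 and 4.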
